A study of Homo sapiens with 2 samples.

How the data were processed

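Total RNA of KYN2 cells, a human hepatocellular carcinoma line, was measured on Illumina HumanWG-6 BeadChips, on which beads carrying gene-specific probes bind biotin-labelled cRNA. Per the labels' protocols, an HSF1 shRNA plasmid was transfected with Oligofectamine and stable lines were kept under puromycin, RNA was extracted with Trizol and cleaned on columns with DNase I treatment, and cRNA was made with an Ambion MessageAmp kit. The shRNA target given in the labels is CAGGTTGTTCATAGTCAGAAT, a sequence of 21 bases in HSF1. Its place in the transcript was not determined, because no transcript sequence was used here. The labels do not say what the control cells carried. The groups were taken from the labels and hold 1 array each, 2 in all.

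The deposited table of non-normalized values gives, per the file headers, a signal and a detection p for each of 48802 probes on each array. The signals are bead intensity values on a linear scale, with no background correction or normalization recorded per the file headers. The deposited detection columns hold a fraction from 0 to 1 that rises with the signal, although the headers call it a p. It was therefore read as 1 minus the detection p. The authors' processed table, also deposited, holds log2 values centred near 0. Its column medians are 0.00222 for the control array and -0.00275 for the knockdown-labelled array. The scale and direction of that table were settled by comparison. Over probes detected on both arrays, the knockdown minus control difference of its columns followed the log2 ratio of the signals with slope 0.981 and r = 0.996 across probes, which are not independent replicates. Its 2 columns sum to 0 within 0.001 for 3838 probes alone. The baseline of its centring stays unknown, so the table was used for differences alone. The scanner and image software are not given in the sources used here. Standard errors and numbers of beads were not used here.

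Probes were named from the platform annotation of 2016. It gave 1 gene symbol for 27577 probes, several for 13 and none for 21212. Of the named probes, 27540 had a gene number in the NCBI gene table (GRCh38.p14), 37 did not, and 0 symbols changed. Probes with several symbols or none were left out of the gene comparisons. The gene table also gave the order of neighbouring genes, and none of its coordinates is reported.

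Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3. That function fits a normal-exponential background, here inferred from the detection p, adds an offset of 16, applies quantile normalization and takes log2. Each of 18665 genes was represented by its probe with the highest mean level over both arrays. A probe was called detected on an array at a detection p under 0.01. Differences are knockdown-labelled minus control, on the log2 scale. With 1 array per group no test is possible, and a gene was called higher or lower by size alone, at a difference of at least 2-fold on genes detected on both arrays. For a gene detected on 1 array, the level there was set against the higher of the other array's lowest detected level and the gene's own level, and the result is given as "at least". The lowest detected levels were 5.84 on the control array and 5.70 on the knockdown-labelled array; the HSF1 probe that breaks the order of detection values was left out of that minimum. The offset pulls small signals together, so folds of dim genes are understated.

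Of the genes detected on both arrays, the 12 with the largest difference each way were named, as were the 4 each way with the largest at-least fold among genes detected on 1 array. Names without an official symbol were skipped, which removed 1 gene from the lower group. HSF1 was reported for every probe. Within each gene list, up to 4 members with the largest difference among those detected on both arrays were named, and any member of the HSF1 target chaperones. These rules, 40 gene lists and most alternatives were fixed before the data were examined. A list with at least 5 members detected on either array was described by its median difference. The percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins, describes these 2 arrays and is no test of the condition. A list was said to stand apart when its median lay in the lowest or highest 2.5% of random medians. If members moved independently, 1.8 of the 36 lists large enough would do so by chance. Genes of 1 pathway can move together and some lists share members, so more lists can stand apart without an effect of HSF1.

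The procedure was tested on data simulated from the control array, with most genes unchanged. The noise had an assumed SD of 0.3 on the log2 scale, made smaller toward background. Counts are over the 7848 genes detected on both simulated arrays. Changed genes that fell below detection are left out, so recovery of dim genes is overstated. The procedure called 20 of 43 genes changed 2-fold, 35 of 40 changed 3-fold, 45 of 45 changed 4-fold and 34 of 34 changed 8-fold, and 4 of 7686 unchanged genes. Of 100 simulated lists of 20 genes without a shift, 3 stood apart, and all 100 did so with a shift of 0.8. The simulated noise was independent between probes, so these lists do not cover genes that move together. The number of arrays limits the precision throughout. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

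Alternatives covered no background correction, an offset of 50, scaling to the median of detected probes, cyclic loess, the authors' processed values, and the mean of a gene's detected probes. Others were a detection p under 0.05, no detection filter, 1.5-fold and 3-fold thresholds, and brighter genes alone. Chosen after seeing the data were the other HSF1 probe, the HSF1 ratio that its detection values allow, genes with 2 or more probes past the threshold, the lower count without HSF1, lists of members detected on both arrays, and lists with 1-array members at their bound.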

Results

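Gene expression was compared between KYN2 cells stably expressing an shRNA against HSF1 and control KYN2 cells. KYN2 is an established line of human hepatocellular carcinoma, the commonest primary liver cancer. HSF1 (heat shock factor 1) is the transcription factor that switches on genes of molecular chaperones when proteins misfold, and many tumour cells depend on it. The comparison asks which genes in these cells change with the amount of HSF1. Each group was measured on 1 BeadChip array, and nothing in the labels describes further cultures, so no difference below has a replicate check and no p-value is given. Signals ran from 36.4 to 23895 on the control array, with a median of 61.5, and from 36.3 to 24818.2 on the array labelled HSF1 knockdown, with a median of 59.8. Of 48802 probes, 11707 were detected on the control array and 12200 on the knockdown-labelled array, and 10804 on both.

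The probes for HSF1 itself did not settle whether its transcript was lower on the knockdown-labelled array. The array carries a pair of HSF1 probes. The brighter probe, ILMN_1667060, had a signal of 164.3 on the control array and 58.2 on the knockdown-labelled array, which is 2.82-fold lower. After background correction and normalization the difference was -2.29 on the log2 scale, or 4.89-fold lower, and in the authors' processed values it was -1.09. The deposited detection values of the same probe ran the other way. They were 0.99473 on the control array and 1.0 on the knockdown-labelled array, where 1.0 is the strongest detection possible. On that array, 459 other probes with signals within 0.1 of 58.2 had detection values from 0.754 to 0.764, and the 10275 other probes with a detection value of 1.0 had signals of at least 119.7. On the control array, the 498 other probes with a detection value of 0.99473 had signals from 113.4 to 122.6. Taken from detection values alone, the log2 ratio could not lie below -0.035. Read from the signal alone, the knockdown-labelled level was not well above background, and the difference on the normalized scale was then at least 2.36-fold. The dimmer probe, ILMN_1665621, had signals of 77.9 and 81.3, a difference of 0.16, with detection p values of 0.0329 and 0.0171, so it was not called detected on either array. Because of this disagreement the arrays are named by their labels throughout, and each direction below rests on those labels.

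**Figure D1:**
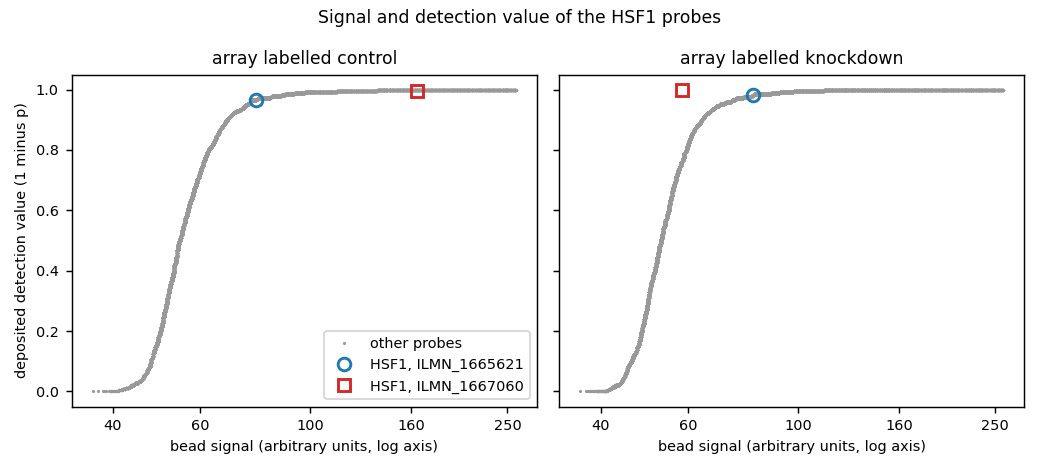
Bead signal (arbitrary units, log axis) against the deposited detection value (1 minus p, no unit) on the control and knockdown-labelled arrays, for the dimmer part of the signal range; grey points are other probes and open symbols the HSF1 probes. Detection rises with signal along a single curve on each array, and the brighter HSF1 probe lies off it on the knockdown-labelled array, at signal 58.2 and detection value 1.0. This probe also breaks the order on the control array, at signal 164.3 and detection value 0.99473, where other probes near that signal have 1.0.

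Differences between the arrays were many and went both ways in similar numbers, a balance that the normalization partly builds in. Of 7511 genes detected on both arrays, 743 (9.89%) were at least 2-fold higher on the knockdown-labelled array and 779 (10.4%) at least 2-fold lower. The lower count includes HSF1 by its signal, which its detection values contradict, and is 778 without it. At 4-fold the counts were 125 higher and 84 lower, the latter again with HSF1 by its signal, and at 8-fold 28 and 8. Among genes detected on both arrays, the strongest increases were in RAB17 and S100A4, and the strongest decreases in ANGPTL8 and KLF2. As groups, genes of DNA replication, mitosis and ribosome assembly were lower, and genes of cholesterol synthesis and NF-kB signalling were higher. A further 794 genes were detected on the knockdown-labelled array alone, 189 of them at least 2-fold above the control array's limit, and 517 on the control array alone, 144 of them at least 2-fold. The median difference was -0.06 and the interquartile range 0.98 on the log2 scale. Levels correlated across genes with r = 0.888, where genes are not independent replicates. The SD of a single probe's difference, estimated from the disagreement of 2 probes of 1 gene over 1577 genes, was 0.34. The spread between the 2 probes is wider than that. This SD covers probe error and leaves out variation between cultures.

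**Figure D2:**
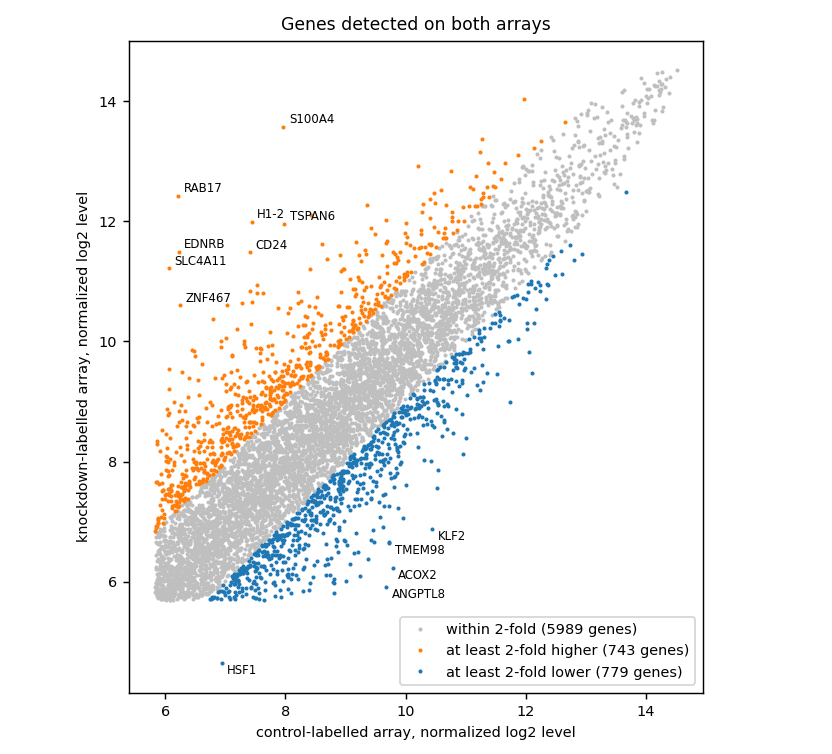
Normalized log2 level on the control array against that on the knockdown-labelled array for 7511 genes detected on both; orange points are the 743 genes at least 2-fold higher and blue points the 779 at least 2-fold lower. RAB17 and S100A4 lie farthest above the diagonal, and the lowest blue point is HSF1, whose level there comes from the signal of 58.2.

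RAB17 and S100A4 had the largest increases among genes detected on both arrays. RAB17, a small GTPase of epithelial vesicle traffic, rose 74.1-fold, from a signal of 115.0 to 5231.2. S100A4, a calcium-binding protein linked to cell motility and metastasis, rose 48.7-fold, from 299.3 to 11204.8, and both its probes did so by 5.53 or more on the log2 scale. EDNRB, the endothelin receptor type B, rose by 5.27 and SLC4A11, a membrane ion transporter, by 5.15. The linker histone gene H1-2 rose by 4.55 and the zinc finger gene ZNF467 by 4.36. CD24, a surface glycoprotein of progenitor cells, rose by 4.07 and the tetraspanin gene TSPAN6 by 3.97. TSPAN6 lies on chromosome X within a stretch of 63 expressed genes whose median difference was 0.66. COBLL1 rose by 3.67, the heme-binding plasma protein gene HPX by 3.59, the membrane progestin receptor gene PAQR8 by 3.57 and CCDC92 by 3.48. Among genes detected on the knockdown-labelled array alone, the betaine and GABA transporter SLC6A12 was at least 93.4-fold higher and the liver-intestine cadherin CDH17 at least 37.1-fold. VNN2, of the vanin family, was at least 32.1-fold higher and the kinase gene SGK1 at least 25.6-fold. Several of these genes lay near the detection limit on the control array, where the background correction sets the size of the fold. The RAB17 difference of 6.21 on the log2 scale was 5.59 without that correction.

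ANGPTL8, KLF2 and ACOX2 had the largest decreases among genes detected on both arrays. ANGPTL8, a secreted regulator of triglyceride clearance, was 13.6-fold lower, from a signal of 910.7 to 100.7. The transcription factor gene KLF2 was 11.9-fold lower and ACOX2, a peroxisomal oxidase of bile acid synthesis, 11.7-fold lower. TMEM98 was 8.49-fold lower, the pseudouridine synthase gene PUS7 8.36-fold and the fatty acid hydroxylase gene CYP4F11 8.03-fold. RGS10, a regulator of G protein signalling, was 8.03-fold lower and ADAP2 was 7.94-fold lower. ITPKA, a kinase of inositol phosphates, was 7.78-fold lower and IMPDH1, an enzyme of guanine nucleotide synthesis, 7.44-fold lower. CDCA7, a gene of cycling cells, was 7.11-fold lower and TIPIN, which protects stalled replication forks, 7.07-fold lower. Detected on the control array alone were GTSF1, at least 24.5-fold lower on the knockdown-labelled array, and GPAM, which starts triglyceride assembly in mitochondria, at least 13.4-fold lower. VAV3 was at least 12.9-fold lower and the cancer-testis antigen gene MAGEA9B at least 11.5-fold lower. The MAGEA9B probe may also bind a near-identical gene copy.

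Of 36 gene lists with at least 5 detected members, 11 stood apart from matched random lists. By chance 1.8 would do so, but only if members moved independently. Genes of the same pathway can move together and some lists share members, so 11 against 1.8 is no measure of an excess. The 3 lower lists were DNA replication, mitosis and ribosome biogenesis. The 8 higher lists were cholesterol synthesis, NF-kB targets, biliary and progenitor markers, p53 targets, interferon-stimulated genes, antigen presentation, integrins and matrix proteases, and lysosome and autophagy.

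**Figure D3:**
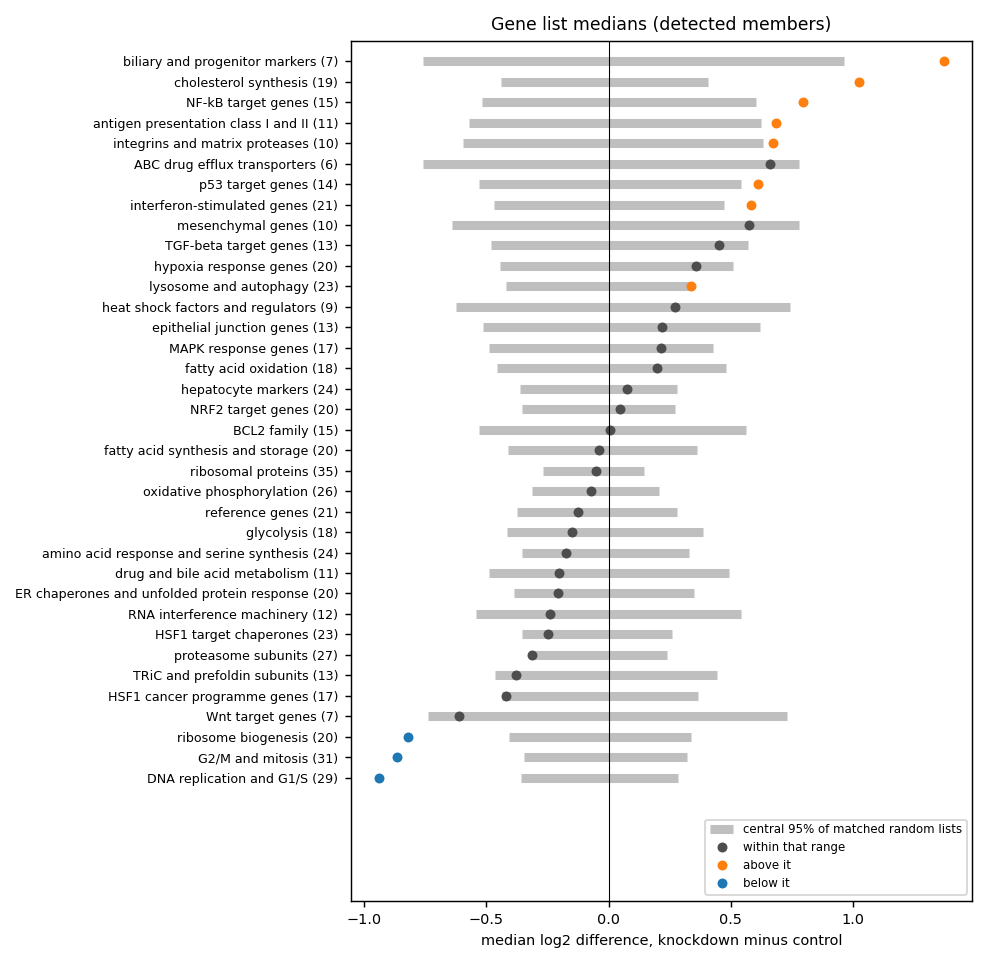
Median log2 difference (knockdown-labelled minus control) of 36 gene lists, with the number of detected members in brackets; grey bars span the central 95% of 10000 matched random lists, and points are orange above, blue below and dark within that range. DNA replication lies lowest at -0.94, and cholesterol synthesis, at 1.02, lies farthest outside its grey bar among the higher lists.

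Genes that cells use to copy DNA, divide and build ribosomes were lower together on the knockdown-labelled array. Of 28 genes of DNA replication and the G1/S transition detected on both arrays, 12 fell at least 2-fold, 0 rose and 16 lay within 2-fold. They included CDC45 (-2.28), which activates the replicative helicase, RRM2 (-2.13), of the enzyme that makes deoxynucleotides, GINS2 (-1.91) and the helicase subunit MCM2 (-1.62). Of 30 genes of G2/M and mitosis, 11 fell, 0 rose and 19 lay within 2-fold, among the falls the kinesin gene KIF2C (-1.77), the cyclin gene CCNA2 (-1.36), the mitotic kinase gene PLK1 (-1.29) and PTTG1 (-1.26), which encodes securin. Of 19 ribosome biogenesis genes, 8 fell, 0 rose and 11 lay within 2-fold, with RRP9 at -2.45, RRS1 at -1.75, PPAN at -1.52 and PES1 at -1.39. The medians were -0.94 over 29 detected replication genes, -0.86 over 31 mitosis genes and -0.82 over 20 ribosome biogenesis genes. Each median lay below those of all 10000 matched random lists. With members detected on 1 array set at their bound, these medians were -0.91, -0.84 and -0.82. Ribosomal protein genes themselves did not stand apart, with 1 of 35 higher (RPS23, 1.84), 0 lower and a median of -0.05 at the percentile 43.9.

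**Figure D4:**
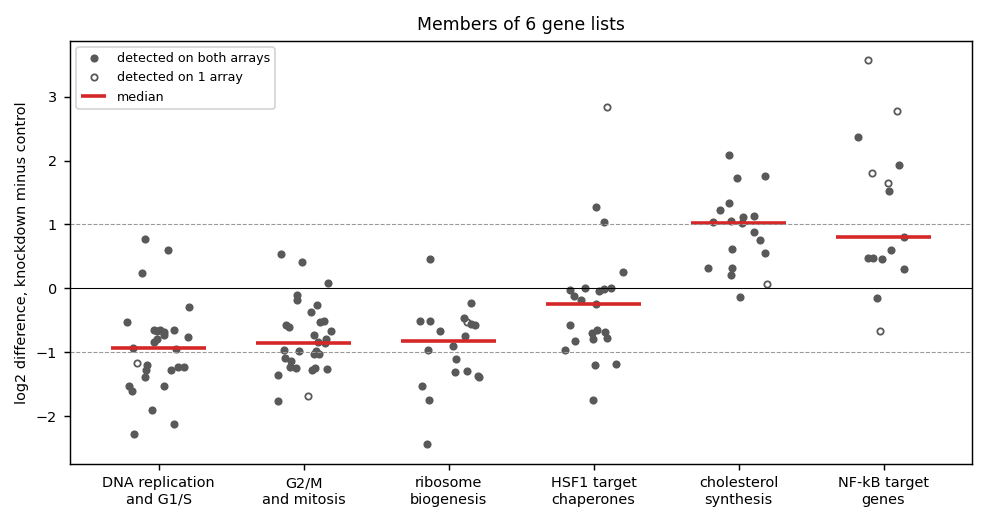
Log2 difference (knockdown-labelled minus control) of each detected member of 6 gene lists; filled points were detected on both arrays, open points on 1, red bars are medians and dashed lines mark 2-fold. Most members of the 3 proliferation and ribosome lists lie below 0, most of the cholesterol list above 0, and the HSF1 target chaperones spread around a median of -0.25.

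Most chaperone genes that HSF1 is known to drive lay below 0, few of them by 2-fold. Whether their list stood apart depended on 1 member. Of 22 such genes detected on both arrays, 3 fell at least 2-fold, 2 rose and 17 lay within 2-fold. The falls were in HSPA4L (-1.76), the co-chaperone gene BAG3 (-1.20) and HSPA8 (-1.19), which encodes the constitutive Hsc70. The rises were in the small heat shock protein gene CRYAB (1.27) and in DNAJB6 (1.03), and HSPB8, detected on the knockdown-labelled array alone, was at least 1.47 higher. Within 2-fold lay the mitochondrial chaperonin pair HSPD1 (-0.96) and HSPE1 (-0.68), the Hsp90 genes HSP90AB1 (-0.83) and HSP90AA1 (-0.78), and the heat-inducible genes HSPA1B (-0.58), DNAJB1 (-0.04) and HSPH1 (0.26). The HSPA1B probe may also bind its near-identical copy HSPA1A. In all, 17 of 23 detected members lay below 0, with a median of -0.25 at the percentile 10.6. With members detected on both arrays alone, which leaves out HSPB8, the median was -0.41 at the percentile 0.74, past the lower bound. HSPB8 had entered the list through the array on which it was higher. DNAJB6 lay under 2-fold in 3 of 6 alternative settings, at 0.73 with the mean of its detected probes.

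The other lists of protein quality control genes did not stand apart in the main setting either. TRiC and prefoldin subunits, which fold actin and tubulin, had 1 of 13 higher (CCT5, 1.30) and 1 lower (PFDN6, -1.79), with a median of -0.38 at the percentile 6.54. Genes of the HSF1 programme of cancer cells, which differs from the heat shock response, had 4 of 16 lower and 0 higher. These were CDC25A (-1.28), HSPA8 (-1.19), UBE2T (-1.17) and TTF2 (-1.05), and the list median was -0.42 at the percentile 2.9. Proteasome subunits had 1 of 27 higher (PSMA2, 1.21), 1 lower (PSMC3, -1.02) and a median of -0.31 at the percentile 3.2. Chaperones of the endoplasmic reticulum and genes of the unfolded protein response had 2 of 19 higher (PPP1R15A, 1.71, and ATF3, 1.51) and 2 lower (SDF2L1, -1.71, and HSPA5, -1.14), with a median of -0.21 at the percentile 17.7. Of the heat shock factors and their regulators, 8 were detected on both arrays and 0 were higher. CDK8 was lower (-1.10), HSF1 counts as lower by its signal with its direction unsettled, and the median was 0.27, or 0.25 at bounds, at the percentile 78.6. The HSF1 cancer programme stood apart as lower in 7 of 10 alternative settings, and the proteasome in 2 of 10. The cancer programme list shares HSPA8 and HSP90AB1 with the chaperone list and CCT6A with the TRiC list. It also holds cell cycle genes such as CDC25A, CDC6 and CCNB1, so its median is not independent of the chaperone and proliferation genes. CDK8 lay under 2-fold in 4 of 6 alternative settings, at -0.80 without background correction, and HSPA5, PSMC3 and TTF2 in 3 of 6 each.

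Genes of cholesterol synthesis were higher together. Of 18 detected on both arrays, 10 rose at least 2-fold, 0 fell and 8 lay within 2-fold. They included the sterol oxidase MSMO1 (2.08), the desaturase SC5D (1.76), NSDHL (1.73) and TM7SF2 (1.33), which all act on sterols late in the pathway. The median over 19 detected members was 1.02, a 2.03-fold increase, above those of all 10000 matched random lists. The other lipid lists did not stand apart. Fatty acid synthesis and storage had 3 of 16 higher (LPIN1, 1.29, DGAT1, 1.02, and SCD, 1.01) and 0 lower, with a median of -0.04 at the percentile 51.8. Fatty acid oxidation had 1 of 16 higher (ACAA2, 1.41) and 2 lower (EHHADH, -1.76, and CPT1A, -1.18), with a median of 0.20, or 0.16 at bounds, at the percentile 80.5. DGAT1, SCD and CPT1A lay under 2-fold in 3 of 6 alternative settings each.

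NF-kB target genes, interferon-stimulated genes and antigen presentation genes were higher on the knockdown-labelled array. The myeloid cell markers LYZ and CD14, named after their values were seen, moved with them, detected on that array alone at least 3.53 and 1.96 higher, while CD68 was at -0.50. Of 10 NF-kB targets detected on both arrays, 3 rose, 0 fell and 7 lay within 2-fold. The rises were in the transcription factor gene IRF1 (2.37), the NF-kB inhibitor gene NFKBIA (1.93) and mitochondrial superoxide dismutase, SOD2 (1.53), while NFKB1 was at 0.80. The median over 15 detected members was 0.80 at the percentile 99.3, and 0.48 with the 5 members detected on 1 array at their bound. Of 14 interferon-stimulated genes, 4 rose, 1 fell and 9 lay within 2-fold, including IRF9 (2.13), the peptide transporter subunit TAP1 (1.53), the ubiquitin-like modifier ISG15 (1.39) and, in the other direction, LY6E (-2.42). The median over 21 detected members was 0.58 at the percentile 99.1, and 0.56 at bounds. It lay at the percentile 96.7, inside the bounds, with members detected on both arrays alone. Of 10 antigen presentation genes, 4 rose, 1 fell and 5 lay within 2-fold, with TAPBP (2.42), HLA-DMA (1.79) and TAP1 higher and TAP2 (-1.16) lower. Their median over 11 detected members was 0.69 at the percentile 98.5. This list and the interferon list share TAP1, PSMB8 and PSMB9, so they are not independent. TAP2 lay under 2-fold in 3 of 6 alternative settings.

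Stress and growth signalling genes moved in part. Of 12 p53 target genes detected on both arrays, 3 rose, 0 fell and 9 lay within 2-fold. The rises were in the cell cycle inhibitor CDKN1A (3.36), the secreted stress factor GDF15 (1.96) and GADD45A (1.64). Within 2-fold lay ZMAT3 (0.76), whose 3 detected probes ran from -0.77 to 0.76. TNFRSF10B, XPC, TP53I3, BAX and TIGAR, also within 2-fold, lay below 0. The median over 14 detected members was 0.61 at the percentile 98.7, and 0.51 at bounds. The list stood apart in 5 of 10 alternative settings, and its percentile fell as low as 69.3. In the BCL2 family, which controls mitochondrial apoptosis, 2 of 11 genes detected on both arrays rose, BCL2L13 (1.70) and BCL2L1 (1.12), and 0 fell. Named after their values were seen, HRK and BCL2A1, on the control array alone, were at least 1.28 and 0.48 lower. PMAIP1, on the knockdown-labelled array alone, was at least 0.96 higher, and BMF, also there alone, had a bound of 0. The family's median was 0.01 at the percentile 53.1. Of 15 genes that respond to MAPK signalling, 5 rose and 1 fell, among the rises the feedback inhibitors SPRY4 (2.43) and DUSP5 (1.99) and the transcription factor genes FOS (1.79) and ETV4 (1.52). Their median was 0.21 at the percentile 86.2. TGF-beta targets had 2 of 11 higher (TGFBI, 2.27, and TGFBR2, 1.45), 0 lower and a median of 0.45 at the percentile 94.2. Wnt targets had 3 of 6 lower (LEF1, -1.66, BMP4, -1.52, and CCND1, -1.09), 0 higher and a median of -0.61, or -0.56 at bounds, at the percentile 5.2. With the 6 members detected on both arrays alone, the Wnt median was -0.83 at the percentile 0.96, past the lower bound.

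Liver identity genes went both ways. Of 20 hepatocyte markers detected on both arrays, 5 rose and 4 fell. HPX (3.59) and the liver transcription factor FOXA1 (2.58) were higher, the plasma glycoprotein AHSG (-2.23) and apolipoprotein B, APOB (-1.91), were lower, and 11 lay within 2-fold. The median was 0.08 at the percentile 78.6, and with cyclic loess normalization 0.40 at 98.6. Drug and bile acid enzymes had 2 of 9 higher (UGT1A6, 1.66, and CYP27A1, 1.42) and 2 lower (UGT1A1, -2.64, and SULT2A1, -1.44), with a median of -0.20 at the percentile 26.4. That median turned to 0.14 with a detection p under 0.05 and was -0.45 with members detected on both arrays alone. SULT2A1 lay under 2-fold in 1 of 6 alternative settings. UGT1A1 and UGT1A6 share most of their exons, so a probe may read both. Of 15 biliary and progenitor markers with a probe, 7 were detected, and all 7 lay above 0. The biliary keratin genes KRT7 and KRT19 were among those detected on neither array. Of the 4 detected on both arrays, CD24 (4.07) rose and 3 lay within 2-fold. SOX9, EPCAM and ANXA3, named here after their values were seen, were detected on the knockdown-labelled array alone, SOX9 at least 3.46 higher. Members detected on that array alone lie above 0 largely through the detection rule itself. The list median was 1.37 at the percentile 99.8, and 0.57 at bounds. The 4 members detected on both arrays were too few for a percentile.

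Among genes of cell shape and adhesion, integrins and matrix proteases were higher as a list, and the mesenchymal and epithelial junction lists did not stand apart. Integrins and matrix proteases had 2 of 8 higher (ITGAV, 1.56, and ADAM10, 1.20), 0 lower and a median over 10 detected members of 0.67 at the percentile 98.2. Mesenchymal genes had 2 of 6 higher (S100A4, 5.61, and TGFBI, 2.27) and 1 lower (THBS1, -1.78), with a median of 0.57, or 0.51 at bounds, at the percentile 92.6. Epithelial junction genes had 1 of 11 higher (JUP, 1.92), 0 lower and a median of 0.22, or 0.00 at bounds, at the percentile 74.0. That median turned to -0.30 with the mean of each gene's detected probes and to -0.23 with members detected on both arrays alone. The mesenchymal list passed the upper bound in 4 of 10 alternative settings.

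Lysosome and autophagy genes were higher, while most other metabolic lists did not stand apart. Of 22 lysosome and autophagy genes detected on both arrays, 6 rose, 1 fell (SQSTM1, -1.13, chosen after its value was seen) and 15 lay within 2-fold. The rises included the lysosomal membrane protein LAMP2 (2.04), GABARAPL1 (1.66), the sialidase NEU1 (1.58) and cathepsin D, CTSD (1.43). LAMP2 lies in the same chromosome X stretch as TSPAN6. The median over 23 detected members was 0.34 at the percentile 97.52, just past the bound, and the percentile was 97.4 with a detection p under 0.05. Hypoxia response genes had 6 of 18 higher, including VEGFA (2.23), PFKFB3 (1.98) and the glucose transporter SLC2A1 (1.72), and 2 lower, with P4HA2 at -1.86 and a median of 0.36 at the percentile 91.8. Without a detection filter their percentile was 98.0. Of glycolysis genes detected on both arrays, 3 of 15 were higher and 3 lower (LDHB, -2.31, PFKM, -2.07, and HK2, -1.74). Named after their values were seen, PFKL and SLC2A2, on the control array alone, were at least 1.55 and 1.42 lower. PFKP, on the knockdown-labelled array alone, was at least 0.07 higher. The glycolysis median was -0.15 at the percentile 27.6. Oxidative phosphorylation had 0 of 26 higher, 1 lower (UQCRC2, -1.25) and a median of -0.07 at the percentile 41.0.

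Among redox and amino acid genes, NRF2 targets had 3 of 19 lower and 0 higher. These were sulfiredoxin, SRXN1 (-2.76), glutathione reductase, GSR (-1.62), and thioredoxin reductase, TXNRD1 (-1.03), in a list whose median was 0.05 at the percentile 72.3. ME1, named after its value was seen, was detected on the control array alone and was at least 1.76 lower. Amino acid response and serine synthesis genes had 3 of 22 higher and 2 lower, with the transporters SLC38A2 at 1.86, SLC7A5 at -1.84 and SLC1A5 at -1.67 and a median of -0.18 at the percentile 18.0. Of 3 metallothioneins detected, MT1X (-1.67) was lower and 2 lay within 2-fold. ABC drug efflux transporters had 1 of 5 higher (ABCC5, 1.23), 0 lower and a median of 0.66, or 0.63 at bounds, at the percentile 95.9. Their percentile was 99.3 with members detected on both arrays alone and 98.2 without a detection filter, both past the upper bound. Genes of the RNA interference machinery, through which an shRNA acts, had 1 of 12 higher (AGO3, 1.08) and 1 lower (TARBP2, -1.01), with a median of -0.24 at the percentile 21.9. Reference genes often used for normalization had 2 of 21 higher (POLR2A, 1.07, and B2M, 1.07) and 2 lower (TUBB, -1.49, and SNRPD3, -1.05), with a median of -0.12 at the percentile 30.2. TARBP2 and SNRPD3 lay under 2-fold in 5 of 6 alternative settings, AGO3 in 3, and B2M and TXNRD1 in 2.

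Markers of other cell types were mostly not detected. Of 12 endothelial markers, 0 were detected on either array. Of 13 fibroblast markers 1 was detected, FBLN1, which was 2.10 higher. Of 18 blood and immune cell markers with a probe, 3 were detected. These were CD68, CD14 and LYZ, with the values given beside the immune gene lists.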

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

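The tests of the HSF1 probe reported in this part were chosen after its values were seen. The deposited detection values are not part of the expression differences, and in them the brighter HSF1 probe stood out. Its detection value was 1.0 on the knockdown-labelled array, where its signal was 58.2, and 0.99473 on the control array, where its signal was 164.3. It was the only probe of 48802 on each array that broke the rise of detection with signal. Rounding of the signals to 1 decimal is argued against, because on the knockdown-labelled array the gap to other probes of the same signal was 0.236 and the widest spread at any 1 signal was 0.0145. A loose tie between signal and detection in general is argued against as well, since 0 steps remained on either array without this probe. Whether HSF1 mRNA was lower in the knockdown-labelled cells, the explanation that the design gives, stays open, because the other probe differed by 0.16 and was not well above background at detection p values of 0.0329 and 0.0171. Which of the deposited numbers is the measured one could not be settled from these files.

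Probes without a single gene name, 21212 with none and 13 with several, took no part in the gene comparisons, and 278 of them were detected on the knockdown-labelled array alone, against 163 on the control array alone. Of 21225 such probes, 1458 were detected on both arrays, 131 of them at least 2-fold higher and 133 at least 2-fold lower.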

How the results depend on the processing

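No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out in turn. Alternatives that use the other HSF1 probe, the HSF1 detection values, genes with several probes, or changed list membership were chosen after seeing the data. The HSF1 difference of -2.29 was -1.47 without background correction and -1.41 with an offset of 50. Those 2 settings leave the background in or add a larger offset, which pulls small signals together by construction. It was -1.09 in the authors' processed values, and the cause was not tested. With the other HSF1 probe it was 0.16, the opposite direction. At the lowest ratio that the brighter probe's detection values allow it was -0.035. For these 2 values the cause was not tested either. The 743 higher genes became 1220 with no detection filter, where more genes are tested, 1562 at 1.5-fold, 244 at 3-fold, 363 among brighter genes and 91 among genes with 2 or more probes all past 2-fold. The 779 lower genes became 1676, 219, 331 and 93 in the last 4 of these settings, and 778 with HSF1 left out, also chosen after seeing the data. Of the genes called in the main setting, 283 have 2 or more detected probes, which limits the counts of 91 and 93. In the other settings the higher count ran from 559 to 913 and the lower count from 537 to 1080, within 1.5 times. Higher genes made up 48.1% to 54.0% of calls across normalizations and filters, and no scaling moved the median of all genes by 0.1. Each setting puts the 2 arrays on a common scale, so a net rise or fall of all genes could not be seen. Between 10 and 14 lists stood apart in each of 10 alternatives, against 11. DNA replication, mitosis, ribosome biogenesis, cholesterol synthesis, NF-kB targets, antigen presentation, and integrins with matrix proteases stood apart in all 10, and biliary and progenitor markers in all 9 that left it 5 members. Of 359 list medians under alternatives, 326 kept their call or value, 7 lost a call, 19 gained one and 7 moved, with 0 called medians reversed. Medians that changed sign in at least 1 alternative, none of which stood apart in the main setting, were those of hepatocyte markers, drug and bile acid metabolism, the BCL2 family, epithelial junctions, fatty acid synthesis, ribosomal proteins and NRF2 targets. Of 1146 values for 191 named genes, 1089 stayed on their side of 2-fold, 46 dropped under it, 10 passed it and 1 moved. Signal over background limits the folds of genes near the detection level.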

Other observations

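The tests of signal near background, of second probes and of neighbouring genes were written down before their results were seen; the tests on the proliferation lists and on clonal selection were chosen afterwards. Genes that lie next to each other moved together in 2 stretches of the genome, in the gene order of GRCh38.p14. On chromosome X, from MAGT1 to STK26, 48 of 63 expressed genes lay above 0, 25 were at least 2-fold higher and 5 at least 2-fold lower, with a median of 0.66. Named after their values were seen, the kinase gene STK26 (2.68) and the chromatin remodeller gene SMARCA1 (1.84) lie there, as do LAMP2 (2.04) and TSPAN6 (3.97). On chromosome 6, from DUSP22 to ATXN1, 26 of 37 expressed genes lay below 0, 10 were at least 2-fold lower and 1 higher, with a median of -0.73, including the quinone reductase gene NQO2 (-2.47), the enoyl-CoA isomerase gene ECI2 (-2.06) and TMEM14B (-2.05). Under 5 other normalizations the medians ran from 0.56 to 0.74 on X and from -0.65 to -0.59 on 6. The chromosome 6 stretch is less certain, since 41 of 1000 shuffled gene orders held a window as strong as its -0.75.

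Of 7511 genes detected on both arrays, 1522 differed at least 2-fold, in both directions. Faulty binding of single probes is argued against as the main source for the 283 called genes with a second detected probe. That probe moved the called way in 94.7% of them (exact binomial interval 91.4% to 97.0%), and past 2-fold in 191 (67.5%). The other called genes have no second detected probe and were not covered. Signal near background stays open as a part of it: 21.35% of the 1522 genes (19.3% to 23.5%) lay among the dimmest 1878, where the offset shrinks folds by construction, and the next dimmest 1878 held 503 of them against 288 in the brightest 1878. Blocks of neighbouring genes may account for a small part. The strongest window of 30 genes, on chromosome X, had a median of 1.065, which 0 of 1000 shuffled orders reached. The stretches hold 41 of the 1522 genes (2.69%), among them 5 on X and 1 on chromosome 6 that moved against their stretch. Weaker or shorter blocks elsewhere stay open. Divergence of the 2 cell populations by clonal selection, apart from HSF1, cannot be told apart from an effect of HSF1 with 1 array per group. Whether the control cells also went through puromycin selection is not known, since the labels do not say what they carried. A hypothesis that follows is that the 2 populations differ in copy number on X, which DNA measurements would test.

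Genes of DNA replication, mitosis and ribosome biogenesis were lower together. An intensity-dependent bias between the arrays would shift random lists matched on mean level as well. The list percentiles therefore could not test it, although all 3 medians stayed below the matched random lists with cyclic loess. With cyclic loess, which removes a trend with intensity, the highest of the 3 medians was still -0.79. That argues against such a trend as the source of the 3 medians. A culture that grew more slowly for reasons other than HSF1, such as density at harvest, could give the same picture and cannot be told apart from an effect of HSF1, because there is 1 array per group. The rise of CDKN1A (3.36) in the same cells goes with slower cycling but does not say what led to it.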
